A study of Mus musculus with 4 samples.

How the data were processed

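The 4 libraries were used as the deposited count matrices, which hold raw UMI counts of 55450 genes per barcode. Per the submitters' processing notes and the file headers the counts came from 10x Genomics 3' v3 libraries aligned and counted with Cell Ranger 5.0.1 on the mouse genome GRCm38, and the barcodes had already been filtered, the lowest holding about 500 UMIs. Per the labels the tissue was dissociated with collagenase IV, papain and DNase, red cells were lysed and dead cells removed with beads, with viability above 85%. Reads were not aligned again. Gene positions were taken from the GRCm38 annotation.

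Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The filters, classes, gene lists, comparisons and 12 alternatives were chosen before the data were examined. Chosen after the data were seen were the rule on ties that leaves clusters without a name, 5 further alternatives, the clustering of the macrophage class on its own, the table of how UMIs were spread over cells, the Hox share without Hoxb13, the limits used for Igkc-rich cells and C1qa, and the shares of T cell genes by Il17a.

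Barcodes with at least 500 UMIs, 200 genes and at most 20% mitochondrial UMIs were kept, which left 16967 and 10647 intestinal and 11668 and 12189 brain barcodes (untreated and NPs). Doublets were called with Scrublet per library. Scrublet did not work in the intestine, where its own threshold marked 0.0354% and 0% of barcodes, so a fixed score of 0.25 was used as set for libraries with less than 0.5% marked. That score removed 0.660% and 0.855%, and 2.87% and 2.03% were removed in the brain, leaving 16855, 10556, 11333 and 11942 cells.

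The libraries of a tissue were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and Leiden clustering at resolution 1 with seed 1 gave 28 intestinal and 23 brain clusters. A cluster was named after the class with the largest share of its markers raised, where a marker counted when at least 2-fold above the median over clusters (10 CPM added to each) and found in at least 20% of the cells of the cluster, and at least 3 markers were needed. A cluster stayed unnamed when another class had as many markers among its 10 leading genes, or when it was shallow and had no marker of its class among them. Marker sets covered 22 classes in the intestine and 21 in the brain. Names mean likeness to marker genes only.

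Counts of all cells of a class in a library were added up and divided by the total UMIs of these cells, giving CPM. A class was compared when both libraries held at least 50 cells of it. B cells of the intestine and oligodendrocytes of the brain therefore gave no gene comparison, and the immunoglobulin list in B cells and the myelin and reactive oligodendrocyte list had no result. A gene was of sufficient level with 100 UMIs and 50 CPM in the higher library and at least 0.5 of the level of all other cells there. In classes with few UMIs, 100 UMIs meant a higher CPM in the library with the smaller total. Counts of 2-fold genes and their medians therefore lean there to genes higher in the library with the larger total. Genes named were the 10 largest and 10 smallest ratios in intestinal macrophages or monocytes and in brain microglia, the 3 largest and 3 smallest in up to 5 other classes per tissue, up to 4 members per list, and Il1b in both main classes. Members of lists were not required to lie above the other cells, so low values of genes abundant elsewhere can hold free RNA. Mitochondrial, ribosomal protein, haemoglobin, Gm-numbered and Rik genes were left out of the naming. Where a library held 0 UMIs the ratio was given as a bound, with 3 counts in place of 0.

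Gene lists written from general knowledge covered IL-1 and inflammasome, NF-kB cytokines and chemokines, resident and anti-inflammatory macrophage, lysosome, MHC class II presentation, interferon response, oxidative stress response, immediate early and heat shock, Th17, regulatory T cell, Th1 and cytotoxic, T cell activation, immunoglobulin constant region, epithelial antimicrobial, epithelial tight junction, sex-linked, cell cycle, homeostatic microglia, disease-associated microglia, complement, reactive astrocyte, blood-brain barrier, endothelial activation and myelin and reactive oligodendrocyte genes. A member was measured with 20 UMIs in the higher library and called higher or lower at 1.5-fold. The median log2 ratio was placed among 10000 random lists drawn from 20 bins of expression. Shares were given exact binomial intervals, levels exact Poisson intervals and ratios conditional binomial intervals, all at 95%.

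The alternatives tried were a limit of 10% mitochondrial UMIs, no such limit, a minimum of 1000 UMIs, doublets kept, resolutions 0.5 and 2, each library clustered separately, the mean over cells in place of the sum, the median of gene ratios as scaling, totals without mitochondrial and ribosomal genes, cells thinned to 1000 UMIs, and lower UMI minima of 5 for lists and 50 for genes. Alternatives chosen later left out cells with at least 20 Igkc UMIs, the dendritic-like sub-clusters, the C1qa-low sub-clusters (below 1000 CPM) or the interferon-led microglia, or counted unnamed clusters as immune.

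The method was tested on simulated data drawn by Poisson sampling from the summed counts of the class at the total of each library, with 200 genes changed by known ratios. It tests the counting and the ratios, and not the clustering or the differences between animals. For intestinal macrophages or monocytes, over 805 genes, 2% of 50 genes changed 1.5-fold, 62.7% of 75 changed 2.5-fold and 100% of 75 changed 4-fold were called at least 2-fold different, and 0 of 605 unchanged genes were. For microglia, over 3290 genes, these were 0%, 100% and 100%, and 0 of 3091 unchanged genes. Intervals covered the simulated ratio for 94.5% of genes. A simulated list reached a percentile of 100, and unchanged lists lay at 35.25 and 32.7.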

Results

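Single-cell transcriptomes were measured in 4 libraries of wild-type mouse cells, 2 from the intestine and 2 from the brain. In each tissue 1 library came from untreated mice and 1 from mice given NPs, for 1 week before the intestinal cells were taken and for 2 months before the brain cells were taken. The labels do not spell out NPs, give no number of animals per library, and name a pair of mouse strains of different ages without saying which strain gave which tissue. The series names the colon as the tissue and immune cells of the colon and brain as its subject, while the sample labels say intestine. No further question is stated, so the NPs library of each tissue was compared with the untreated library of the same tissue, and higher and lower always mean the NPs library against the untreated one. The untreated intestinal library held 116394801 UMIs in 20368 barcodes with a median of 2043 UMIs, and the NPs intestinal library held 127772838 UMIs in 19918 barcodes with a median of 2411. The untreated brain library held 70594935 UMIs in 11754 barcodes with a median of 5026.5, and the NPs brain library held 63889853 UMIs in 12226 barcodes with a median of 4638.5. With 1 library per group there were no replicates, so no difference could be set against a replicate error and no p-value was computed. Intervals are 95% intervals and cover counting error only.

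In the intestine, the NPs library held far fewer B cells, T cells and mast cells than the untreated library, and more goblet cells, macrophages or monocytes and fibroblasts. B cell-like cells made up 14.9% of kept cells in the untreated library (2519 of 16855, 14.4 to 15.5%) and 0.0284% in the NPs library (3 of 10556, 0.00586 to 0.0830%). T cell-like cells were at 11.9% and 2.26%, mast cell or basophil-like cells at 2.28% and 0.0663%, and plasma cell-like cells at 3.07% and 1.12%. Goblet cell-like cells, which secrete mucus, were at 7.92% (7.52 to 8.34%) and 40.5% (39.6 to 41.5%), and absorptive epithelium-like cells at 25.7% and 32.8%. Fibroblast-like cells were at 0.748% and 3.61%, and enteroendocrine-like cells at 1.495% and 0.900%. Endothelial-like cells were found only in the NPs library, at 0.881% (93 cells), against 0 of 16855 cells, for which the exact interval allows a share of up to 0.0219%. Macrophages or monocytes were at 0.807% and 3.56% of kept cells and NK cells or ILCs at 0.902% and 0.824%. Among the immune-like cells alone, where the fewer B and T cells raise the shares of the others, macrophages or monocytes went from 2.38% (136 of 5707, 2.00 to 2.81%) to 45.3% (376 of 830, 41.9 to 48.8%), B cells from 44.1% to 0.361%, T cells from 35.0% to 28.8%, NK cells or ILCs from 2.66% to 10.5%, plasma cells from 9.06% to 14.2% and mast cells or basophils from 6.75% to 0.843%. With the C1qa-low sub-clusters of the macrophage or monocyte class left out, a choice made after the data were seen, its share of immune-like cells was 0.376% (21 of 5592) and 42.6% (337 of 791). Clusters left without a name, by a rule on ties that was set after the data were seen, held 30.3% of kept cells in the untreated library and 13.4% in the NPs library. The limit of 20% mitochondrial UMIs bears on these shares, because 16.7% of the barcodes of the untreated library and 46.6% of those of the NPs library lay above it. The difference in the plasma cell share turned to 0.415 points higher with a limit of 10% and to 0.0734 points higher with doublets kept, and the absorptive share turned to 10.2 points lower (-10.2) with doublets kept. Among immune-like cells the T cell difference turned to 1.77 points higher with no mitochondrial limit, 10.7 points higher with the libraries clustered separately and 0.0121 points higher with unnamed immune clusters counted, and the NK cell or ILC difference turned to 2.46 points lower (-2.46) with separate clustering.

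**Figure D1:**
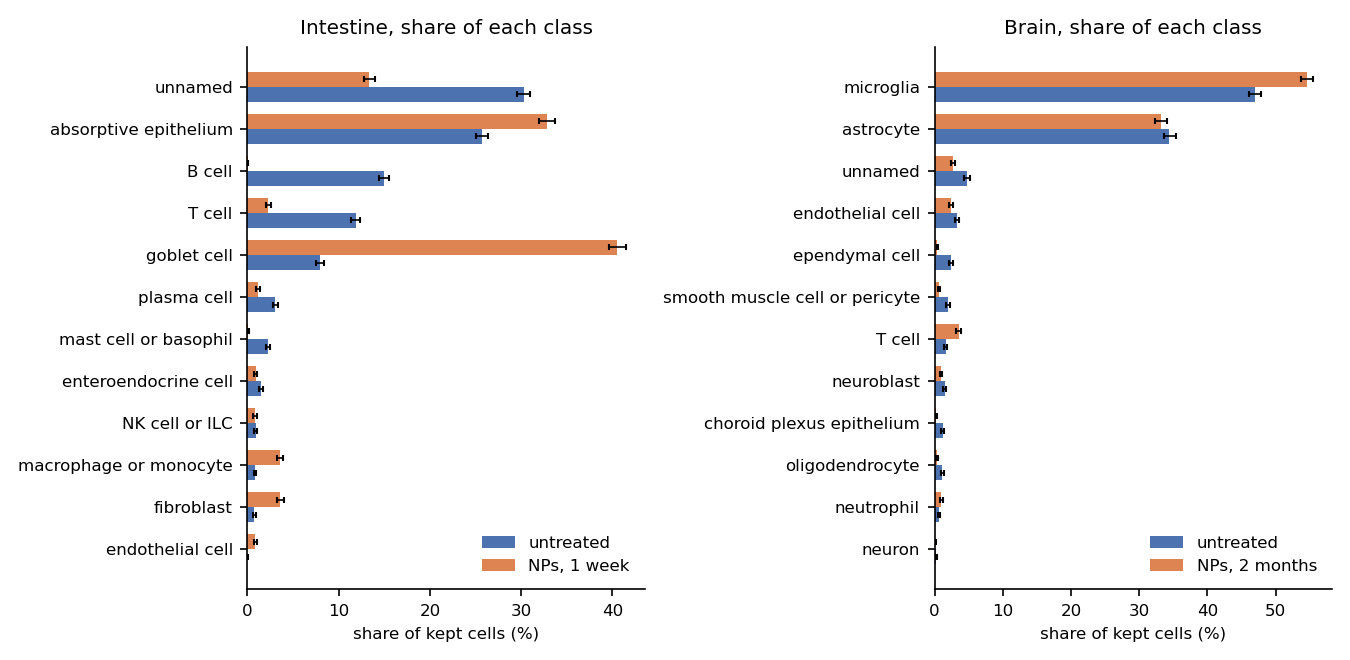
Share of kept cells (percent, horizontal axis) in each class of the intestinal libraries (left) and brain libraries (right), with blue bars for the untreated library, orange bars for the NPs library and exact 95% binomial intervals as error bars. Goblet cells were at 7.92% and 40.5% in the intestine, and microglia at 47.0% and 54.6% in the brain.

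The macrophage or monocyte class of the NPs intestinal library carried more transcripts of chemokines and of genes of resident tissue macrophages. Its cells differed in kind between the libraries, because most of the untreated cells, but few of the NPs cells, lay in sub-clusters low in the macrophage gene C1qa. The largest ratio was that of Pf4, a chemokine of platelets and of some tissue macrophages (ENSMUSG00000029373, GRCm38 chromosome 5, 90772435 to 90773383), which was at 5.12 CPM (UMIs scaled to the total of the class) in the untreated library and 409.6 in the NPs library, a ratio of 80.01 (27.3 to 389). Ccl8, a chemokine that attracts monocytes, was at 35.8 and 2214 CPM, 61.8-fold higher (40.4 to 99.9). Fcrls, Clec4b1 and Folr2, a folate receptor of resident macrophages, each had 1 UMI in the untreated library, with ratios of 62.9, 55.2 (9.76 to 2193) and 48.5 (8.56 to 1929). Over the alternatives Pf4, Clec4b1 and Folr2 came as low as 3.33, 1.87 and 2.03 on the log2 scale, so they stayed higher, Pf4 by a far smaller ratio. With only 1 untreated UMI, the low values of Clec4b1 and Folr2 can be bounds with 3 counts in place of 0. The size of these 2 ratios is therefore uncertain. Art2a-ps was 21.3-fold higher (9.70 to 58.5), Igfbp4 19.5-fold (5.27 to 163) and the kinase gene Pim3 18.3-fold (4.93 to 153). Cp, which encodes ceruloplasmin, had 0 UMIs in the untreated library and was at least 18.7-fold higher. Cxcl13, a chemokine that attracts B cells, was 31.5-fold higher (10.7 to 154), but its UMIs lay in 16 of the 376 cells. Among the genes lower in the NPs library were Siglech, 33.9-fold lower at 488 and 14.4 CPM, Ccr9, 20.4-fold lower, Cox6a2, 37.6-fold lower, and Ly6d, at least 182-fold lower, all of them abundant in plasmacytoid dendritic cells. With the libraries clustered separately Cox6a2 and Siglech turned to 0.73 and 0.67 higher on the log2 scale. Gzmb was at least 102-fold (70.4% of its UMIs lay in the top 1% of cells), Cd7 96.8-fold (32.2 to 477) and Cd8a 61.5-fold lower (25.5 to 193). In the untreated library Gzmb and Cd7 were at 184 and 174 CPM in this class and at 322 and 189 CPM in all other cells. Slpi was 20.6-fold, Iglc3 14.7-fold and Tnni2 8.62-fold lower. Over the alternatives Slpi, Iglc3 and Ccr9 came as close as -0.63, -0.25 and -0.44 on the log2 scale, so these calls were lost, as was that of Pim3 (0.87) when thinned. Il1b, the gene of interleukin-1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), was at 3101 and 2232 CPM, 1.39-fold lower (1.31 to 1.47).

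Of 1329 genes of sufficient level in this class, 245 were at least 2-fold higher and 91 at least 2-fold lower. The median of all of them lay 0.26 higher on the log2 scale, and with that median set to 0 the counts were 179 and 155, so that the share of higher genes went from 72.9% to 53.6%. The rule of 100 UMIs in the higher library favoured higher genes, because the class held 585980 untreated and 1667466 NPs UMIs. With a minimum of 50 UMIs, 290 of 2059 genes were higher and 196 lower (59.7% higher), and their median lay only 0.035 higher. The class was not of one kind: when it was clustered again, after the genes had been seen, 2 sub-clusters had more dendritic cell than macrophage markers and left 98 untreated and 348 NPs cells when taken out, and then Siglech was 0.24 higher on the log2 scale. Sub-clusters rich in the macrophage gene C1qa held 21 untreated and 337 NPs cells, too few for the minimum of 50, and with them alone 275 of 876 genes were at least 2-fold higher and 7 lower. The median of these 876 genes lay 0.57 higher. So few untreated cells rarely reach 100 UMIs for a lower gene, so the rule itself favoured higher genes. The split of 275 and 7 therefore cannot be read as a rise of most genes. A sub-cluster led by Gzmb, Gzma and Ebf1, with a median of 1110 UMIs per cell, held 56 untreated cells and 1 NPs cell, and a sub-cluster led by the neutrophil genes S100a8 and S100a9, with Il1b at 11590 CPM, held 21 and 10. Sub-clusters led by epithelial genes such as Krt18 and Krt8 held 2 and 55 cells and 1 and 21 cells.

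Of the gene lists fixed beforehand, resident and anti-inflammatory macrophage genes showed the largest difference in this class, with 10 of 11 measured members at least 1.5-fold higher and none lower. Their median log2 ratio was 2.88, a percentile of 100 among 10000 random lists of like expression. Only 21 of the 136 untreated cells, but 337 of the 376 NPs cells, lay in sub-clusters rich in C1qa. The lists gave no value in those cells alone, so the list differences of this class can reflect its mix of cells. Mrc1, the mannose receptor, was at 23.9 and 399 CPM (16.7-fold higher), Selenop, which encodes a selenium transport protein, at 116 and 1475 (12.7-fold), Gas6 was 16.5-fold and the scavenger receptor gene Stab1 16.2-fold higher. Of 19 measured NF-kB cytokines and chemokines, 12 were higher and 2 lower, with a median of 0.94 (percentile 100, 0.61 to 1.28 over the alternatives). The monocyte chemokines Ccl7 and Ccl2 were 16.0-fold and 7.66-fold higher, and the neutrophil chemokines Cxcl1 and Cxcl2 8.53-fold and 2.89-fold higher. The lower members were Il23a, 7.97-fold (-0.25 on the log2 scale without the dendritic-like sub-clusters), and Ccl5, 4.75-fold, a chemokine of cytotoxic lymphocytes. Of 23 lysosome genes 14 were higher and 1 lower, with a median of 0.74 (percentile 99.98), which went to 0.48 with the median of all genes set to 0. Cd63 was 3.41-fold, Lamp1 3.18-fold, and the cathepsin genes Ctsd and Ctsb 2.98-fold and 2.71-fold higher. Of 16 immediate early and heat shock genes 7 were higher and 0 lower (median 0.51, percentile 99.3, 0.25 to 0.80 over the alternatives), among them Junb, 4.21-fold, Ier2, 3.00-fold, and Atf3, 2.35-fold.

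The remaining lists went both ways in macrophages or monocytes. Of 11 IL-1 and inflammasome genes 3 were higher and 2 lower, with a median of -0.05 (percentile 54.4) that went to -0.31 with the median of all genes set to 0. The lower members were Il1a, at 131 and 24.0 CPM (5.48-fold), and Il1rn, the receptor antagonist, at 285 and 88.2 (3.23-fold), while the inflammatory caspase gene Casp4 was 2.67-fold and Nlrc4 2.99-fold higher (1.07 to 11.6). The sub-cluster led by S100a8 and S100a9 had Il1a among its leading genes and Il1b at 11590 CPM. It held 21 of the 136 untreated and 10 of the 376 NPs cells, so the lower Il1a and Il1b can reflect the mix of cells, which was not tested. Of 9 MHC class II genes 2 were higher and 1 lower (median 0.38, percentile 94.3, 0.02 to 0.56 over the alternatives), with H2-Ab1 1.77-fold and H2-Eb1 1.73-fold higher and H2-DMb2 2.01-fold lower, none of which held 1.5-fold under every alternative. Of 18 interferon response genes 4 were higher and 3 lower (median 0.19, percentile 82.4, -0.43 to 0.36 over the alternatives), with Ifit3 8.26-fold higher (2.16 to 70.2, and 0.48 on the log2 scale when thinned), Ifit2 2.81-fold higher and Ifit1 1.90-fold lower, but Ifit2 turned to -0.31 when thinned and Ifit1 turned under 3 alternatives. Of 12 oxidative stress genes 2 were higher and 2 lower (median -0.12, percentile 23.9, -0.57 to 0.21 over the alternatives), with the haem oxygenase gene Hmox1 2.68-fold higher and Slc7a11 6.83-fold lower. Of 7 cell cycle genes 1 was higher and 3 lower (median -0.44, percentile 8.48, -1.33 to 0.66 over the alternatives), with Tyms 4.44-fold and Stmn1 2.75-fold lower, both calls being lost with the mean over cells.

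**Figure D2:**
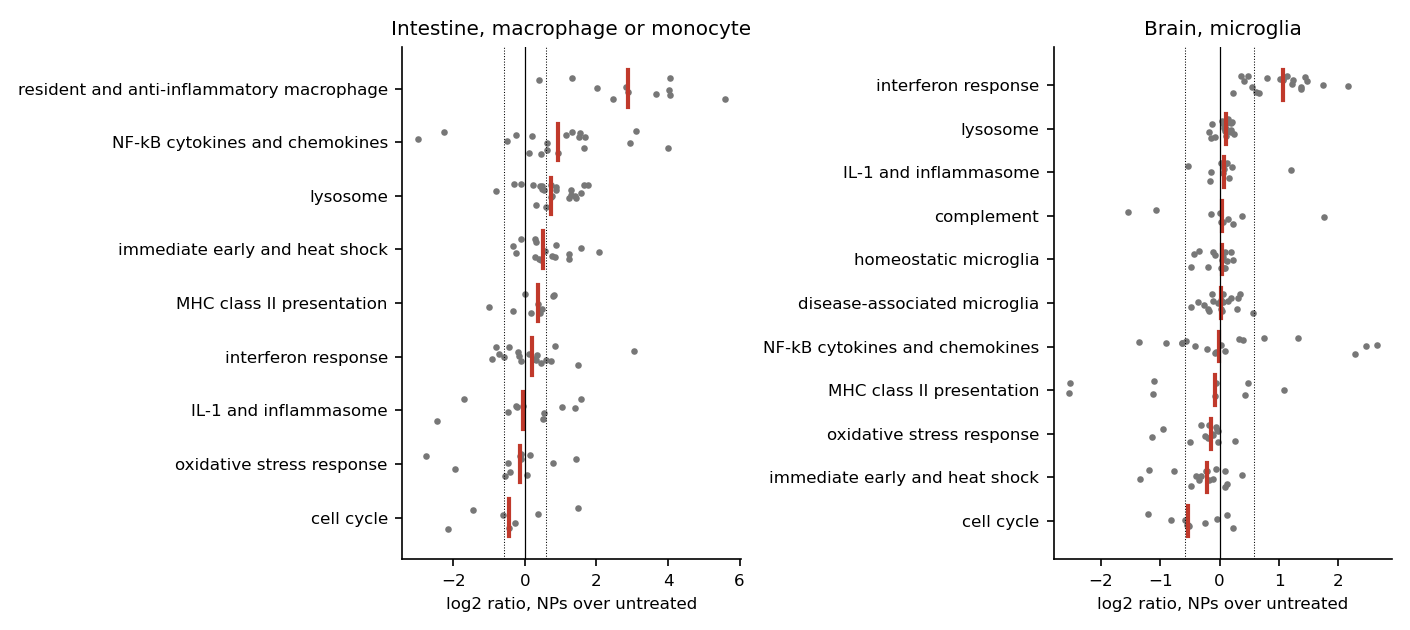
Log2 ratio of CPM, NPs over untreated (horizontal axis), of each measured member (grey points) of the gene lists, with the list median as a red bar, in intestinal macrophages or monocytes (left) and brain microglia (right). Dotted lines mark a 1.5-fold difference, and the medians run from -0.44 for cell cycle to 2.88 for resident macrophage genes in the intestine and from -0.53 for cell cycle to 1.07 for interferon response in the brain.

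The absorptive epithelium of the NPs library carried transcripts of the lectin genes Reg3b and Reg3g that were nearly missing from the untreated library, and far fewer transcripts of interferon response genes. Reg3b, an antimicrobial lectin, had 0 UMIs in the untreated library and 105855 in the NPs library (2290 CPM), and Reg3g went from 0.328 to 513 CPM. Of 11 antimicrobial genes 6 were higher and 5 lower (median 0.89, percentile 98.0, and 1.57 with the lower UMI minimum). Ang4 and Saa3 were 139.7-fold and 50.4-fold higher, Ang4 reaching 25.4 CPM against 904 CPM in all other NPs cells, while Saa1, a serum amyloid gene, was at 4311 and 249 CPM and Lypd8, which holds bacteria off the epithelium, was 4.58-fold lower. All 19 measured interferon response genes were lower (median -2.78, percentile 0), with Gbp2 21.6-fold lower, Isg15 at 2035 and 118 CPM (17.2-fold), Ifi27l2a 14.0-fold and Mx1 13.8-fold lower. Of 9 MHC class II genes 7 were lower and none higher (median -0.70, percentile 1.34), among them H2-Aa, 2.30-fold, and H2-Eb1, 1.98-fold. Of 16 immediate early and heat shock genes 15 were higher (median 1.49, percentile 100), with Hspa1a 11.3-fold, Ier2 6.85-fold and Jun 4.78-fold higher, while the median mitochondrial share of these cells was 4.85% and 8.49%. Of 15 tight junction genes 4 were higher and 4 lower (median -0.19, percentile 3.06, -0.42 to 0.04 over the alternatives), with Cldn15 19.4-fold and Cldn2 7.93-fold higher and Cldn8 5.15-fold lower. Osr2 and Arhgap20 each had 1 UMI in the untreated library and ratios of 3736 (670.3 to 147590) and 2578 (463 to 101870), and the ion transport genes Atp12a, Trpv6 and Fxyd4 were 1483-fold, 921-fold (314.5 to 4469) and 768-fold lower. Of 2956 genes of sufficient level 566 were at least 2-fold higher and 350 lower, the median of all lying 0.23 higher on the log2 scale, and with that median set to 0 the counts were 399 and 442.

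Different clusters held the absorptive and goblet cells of the 2 intestinal libraries, and posterior Hox transcripts differed in these and in other classes. Absorptive cells came from clusters 7 (1466 untreated cells and 0 NPs cells) and 9 (2860 and 1) in one library and from clusters 20 (2 and 1855) and 21 (3 and 1611) in the other, with median depths of 2159 and 10179 UMIs. Hox genes, which mark position along the body axis, were split into posterior (groups 10 to 13) and other members. Posterior members made up 87.8% of Hox UMIs in absorptive cells of the untreated library (87.2 to 88.3%) and 9.13% in the NPs library (8.72 to 9.54%). In fibroblasts they made up 76.2% (99 of 130 UMIs, 67.9 to 83.2%) and 26.7% (153 of 574, 23.1 to 30.5%), and without Hoxb13, a gene known from the distal colon, 62.7% and 25.2%. The shares were 73.1% and 11.8% in goblet cells, 69.0% and 10.4% in enteroendocrine cells, which shared 1 cluster, 67.0% and 4.69% in T cells and 83.3% and 12.4% in macrophages or monocytes.

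**Figure D3:**
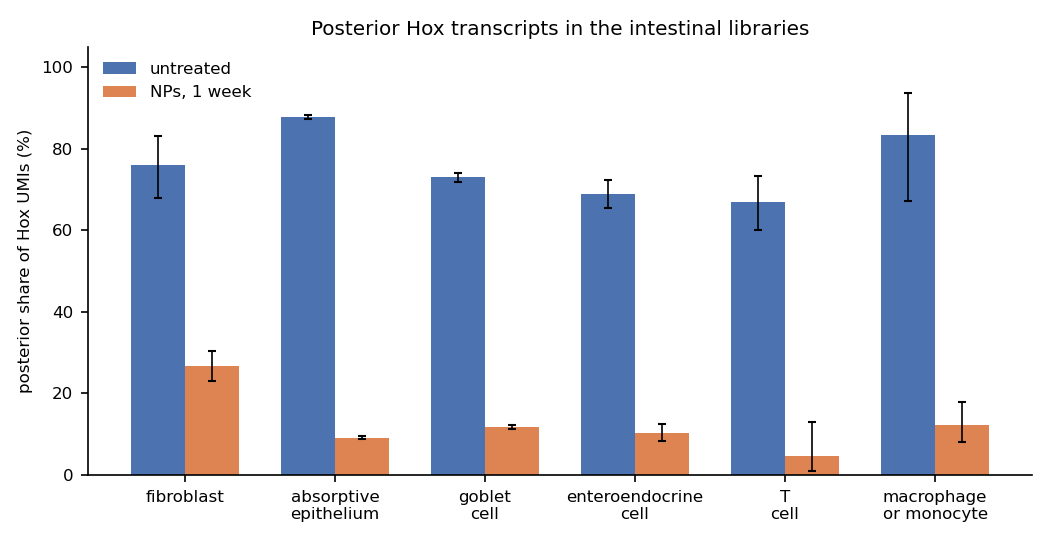
Posterior share of Hox UMIs (percent, vertical axis) in 6 classes of the intestinal libraries, with blue bars for the untreated library, orange bars for the NPs library and exact 95% binomial intervals as error bars. In every class drawn the untreated library was higher, with 76.2% and 26.7% in fibroblasts.

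Goblet cells of the NPs library carried more Car8, a carbonic anhydrase-related gene (73.2-fold, 51.2 to 108.5), and less Slpi (308-fold lower) and Spink1 (42.1-fold lower). Osr2 was 406-fold higher (112 to 3354) on 2 untreated UMIs, Cma1, a mast cell protease gene, was at least 938-fold lower, and 96.5% of the UMIs of Acta2, 84.5-fold higher, lay in the top 1% of cells, its call being lost (0.17) at 10% mitochondrial UMIs. Clusters 3 (988 untreated cells and 1 NPs cell) and 18 (335 and 6) held most goblet cells of the untreated library, and clusters 22 (4 and 2057), 23 (8 and 1525) and 24 (0 and 690) those of the NPs library. Of 3001 genes of sufficient level 156 were at least 2-fold higher and 96 lower. In enteroendocrine cells these were 175 and 61 of 1583, and 109 and 86 with the median of all genes, 0.24 higher, set to 0.

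T cells of the NPs intestinal library carried more regulatory T cell transcripts and more immediate early transcripts. Dapl1 was 39.4-fold lower (10.9 to 326), and Ccr7, which guides naive T cells to lymph nodes, was 9.60-fold lower. Of 8 regulatory T cell genes 6 were higher and none lower (median 1.15, percentile 99.99), with Foxp3, the master regulator, 4.93-fold higher (2.75 to 8.56), Il10 4.22-fold and Tnfrsf4 3.57-fold higher. Of 16 immediate early and heat shock genes 14 were higher (median 1.14, percentile 100), with Hspa1a 5.21-fold, Atf3 4.25-fold and Junb 3.18-fold higher. Of 7 Th17 genes 3 were higher and 3 lower (median 0.34, percentile 96.6, 0.20 to 1.80 over the alternatives), with Ahr 6.41-fold and Rora 2.88-fold higher. Il17a was lower, with 133 UMIs and 1 UMI out of class totals of 6896026 and 650777 UMIs. The direction of Il17a (1.63, 2.10 and 0.69 on the log2 scale) turned with no mitochondrial limit, with doublets kept and with the libraries clustered separately. Of 11 Th1 and cytotoxic genes 4 were higher and 3 lower (median -0.01, percentile 38.9, -0.30 to 0.30 over the alternatives), with Tbx21 2.52-fold and Ifng 2.05-fold higher. Of 9 activation genes 3 were higher (median 0.38, percentile 92.4, 0.22 to 0.73 over the alternatives), with Cd44 2.71-fold and Pdcd1 2.05-fold higher (Pdcd1 0.29 on the log2 scale with separate clustering), and of 12 cell cycle genes 1 was lower and 11 lay between (median -0.37, percentile 0.04, -0.62 to -0.19 over the alternatives). Mir6236 was 7.48-fold higher, and Plin2, 7.39-fold higher, had 51.3% of its UMIs in the top 1% of cells. Clusters 6 (758 untreated cells and 5 NPs cells), 11 (913 and 80) and 14 (327 and 154) made up the class. Leading genes included Lef1 and Dapl1 in cluster 6, Ccl5, Gzma and Gzmb in cluster 11, and Icos and Ctla4 in cluster 14. The mix of T cells thus differed between the libraries. The list and gene differences of this class, the regulatory T cell list and Dapl1 among them, can reflect that mix, which was not tested. Of 1568 genes of sufficient level 48 were at least 2-fold higher and 31 lower, and 71 and 19 with the median of all genes (-0.15) set to 0. In NK cells or ILCs the counts were 23 and 28 of 441, and 35 and 10 with the median (-0.26) set to 0.

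Among the smaller intestinal classes, plasma cells of the NPs library held fewer transcripts of most immunoglobulin constant region genes. Of 12 such genes 3 were higher and 7 lower (median -1.14, percentile 0.01, -1.55 to -0.74 over the alternatives), with Ighm 31.2-fold lower (71.2% of its UMIs in the top 1% of cells), Ighg3 13.1-fold and the light chain gene Iglc3 5.98-fold lower and Igha 1.95-fold higher. Ms4a1, the gene of the B cell antigen CD20, was 41.1-fold lower (13.9 to 200.3), from 112 CPM in untreated plasma cells against 150.3 CPM in all other untreated cells, Apoe was 40.3-fold lower, Cxcl10 was 5.96-fold and Fosb 4.00-fold higher, and Igkv5-43, 22.6-fold higher, rested on 6 cells. Plasma cells came from clusters 0 (341 untreated cells and 1 NPs cell) and 1 (176 and 117), at median depths of 1531 and 7555.5 UMIs. Of 868 genes 28 were at least 2-fold higher and 63 lower, and 51 and 34 with the median of all genes (-0.31) set to 0. Fibroblasts carried Hmcn2 at a ratio of 35.4 (12.03 to 172.5) and Ptn, a heparin-binding growth factor gene, at least 27.5-fold higher, while Ly6g was 96.4-fold lower, from 609 CPM in untreated fibroblasts against 776 CPM in all other untreated cells. Adamdec1, 104-fold higher on 1 untreated UMI (18.6 to 4123), lay in 16 cells, and Cxcl13 and Clu, 296-fold and 72.1-fold lower, rested on 8 and 4 cells, Clu turning to 1.76 higher on the log2 scale with a limit of 10% mitochondrial UMIs. Of 1614 genes in fibroblasts 230 were at least 2-fold higher and 62 lower, and 122 and 111 with the median of all genes, 0.34 higher, set to 0. Xist and Tsix, expressed from the inactive and active X chromosome of females, were measured in both intestinal libraries, Xist at 1044 and 1734 CPM, and Y-linked genes were not.

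In the brain, the NPs library held a larger share of microglia and of T cells and smaller shares of the cells that line the ventricles. Microglia-like cells made up 47.0% of kept cells in the untreated library (5323 of 11333, 46.0 to 47.9%) and 54.6% in the NPs library (6519 of 11942, 53.7 to 55.5%). T cell-like cells were at 1.61% (182 cells, 1.38 to 1.85%) and 3.51% (419 cells, 3.19 to 3.85%), and neutrophil-like cells at 0.653% and 0.988%. Ependymal-like cells were at 2.42% and 0.410%, choroid plexus epithelium-like cells at 1.16% and 0.209%, smooth muscle cells or pericytes at 1.91% and 0.662%, and oligodendrocyte-like cells at 1.10% and 0.368%. Astrocyte-like cells were at 34.4% and 33.2%, endothelial-like cells at 3.26% and 2.34%, neuroblast-like cells at 1.48% and 0.904% and neuron-like cells at 0.238% and 0.100%. Among immune-like cells T cells went from 3.26% to 5.94%, microglia from 95.4% to 92.4% and neutrophils from 1.33% to 1.67%. Clusters without a name held 4.76% and 2.74% of kept cells. Shares are parts of a whole, so smaller shares of several classes raise those of the others. Whether the NPs or the way the tissue was taken gave these differences in brain shares was not tested.

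Few genes separated microglia, the resident macrophages of the brain, between the brain libraries: of 3231 genes of sufficient level 14 were at least 2-fold higher and 11 at least 2-fold lower. The largest ratio outside the immunoglobulin genes was that of Cd300lf, an inhibitory receptor gene of myeloid cells (ENSMUSG00000047798, chromosome 11, 115116214 to 115133992), at 7.88 and 148 CPM, 18.7-fold higher (16.4 to 21.5). Ppfia4 was at 6.98 and 128 CPM, Ldhb, a lactate dehydrogenase gene, at 81.7 and 372 (4.55-fold higher), Slc37a2 was 3.28-fold and Nhlrc3 2.73-fold higher. H2-D1, a class I antigen presentation gene, was at 518 and 1330 CPM (2.57-fold higher), and Rtn4rl1 was 2.502-fold higher. Syt6 was 3.99-fold, the histone gene Hist1h2al 3.80-fold, Actn1 3.54-fold, the calcium channel gene Cacna1a 2.69-fold and Trpm2 2.38-fold lower. The chemokine gene Ccl2 was at 152 and 59.2 CPM (2.56-fold lower), and the heat shock genes Hspa1a and Hspa1b were 2.54-fold and 2.28-fold lower, with Hist1h1d 2.20-fold and H2-DMb1 2.15-fold lower. Il1b was at 72.3 and 49.8 CPM, 1.45-fold lower (1.36 to 1.55), with 64.3% of the untreated UMIs in the top 1% of cells. Jchain, Igkc and Igha stood highest of all, at 321-fold, 212.5-fold and 95.7-fold, but 95.4% of the 17347 Igkc UMIs lay in 1 of 6519 cells, and without it Igkc was at 24.0 against 2.46 CPM. Microglia clusters 4 and 5 were led by stress and immune genes such as Atf3, Klf2, Egr1, Dusp1 and Ccl4, and cluster 2 (2005 untreated and 153 NPs cells) and cluster 8 (407 and 3091) split the class by library.

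Interferon response genes were the list that differed most in microglia: 15 of 20 measured members were higher and none lower, with a median of 1.07 (percentile 100). Rsad2, an antiviral enzyme gene, was at 3.71 and 16.7 CPM, Oasl2 was 3.34-fold, Ifit1 2.76-fold and Mx1 2.72-fold higher. Cluster 3, led by interferon response genes, held 46 untreated and 186 NPs microglia, and without it the median was 0.27, Rsad2 and Mx1 were within 1.5-fold and Ifit1 was lower (-0.27). Homeostatic microglia genes (15 of 15) and disease-associated microglia genes (19 of 19) all lay within 1.5-fold, with medians of 0.04 (percentile 44.75) and 0.03 (percentile 47.9), Selplg 1.40-fold lower and Spp1, osteopontin, 1.47-fold higher, but lower (-1.09) with the libraries clustered separately. All 23 lysosome genes lay within 1.5-fold too (median 0.10, percentile 96.9), among them Npc2, 1.18-fold, and Ctsb, 1.15-fold higher. Of 12 IL-1 and inflammasome genes 1 was higher, Il1rn at 1.21 and 2.80 CPM (0.21 on the log2 scale with separate clustering), and none lower (median 0.07, percentile 75.9), with Nlrp3 1.12-fold and Casp1 1.16-fold higher. Of 18 NF-kB cytokines and chemokines 5 were higher and 4 lower (median -0.02, percentile 25.7), with Il12b 6.27-fold and Ccl5 4.85-fold higher. Of 9 MHC class II genes 1 was higher and 4 lower (median -0.07, percentile 12.2), with H2-DMa 5.81-fold lower. Of 16 immediate early and heat shock genes 3 were lower and none higher (median -0.22, percentile 0), the third being Hsp90aa1, 1.70-fold. Of 14 oxidative stress genes 2 were lower (median -0.15, percentile 0.08), the metallothionein genes Mt2, 2.21-fold, and Mt1, 1.94-fold. Of 10 complement genes 1 was higher and 2 lower (median 0.04, percentile 62.2), with C4b 3.37-fold higher and C3 2.93-fold lower, and of 10 cell cycle genes 2 were lower (median -0.53, percentile 0.45, -1.32 to -0.46 over the alternatives), with Mki67 2.30-fold lower on 35 and 18 UMIs.

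Astrocytes of the NPs brain library differed in few genes, 6 of 3161 at least 2-fold higher and 3 lower, but by a large ratio in Colec12. Colec12, a scavenger receptor of the collectin family (ENSMUSG00000036103, chromosome 18, 9707595 to 9882644), was at 17.2 and 1442 CPM, 83.8-fold higher (75.3 to 93.4), and had UMIs in 92.9% of the 3962 NPs astrocytes. Nhlrc3 was 4.29-fold and Retsat 4.25-fold higher, and Hist1h2al 2.47-fold, the adenosine receptor gene Adora2b 2.08-fold and Efemp1 2.00-fold lower, the last 2 falling just short of 2-fold under some alternatives. Several differences were not particular to astrocytes. Colec12 was also higher in smooth muscle cells or pericytes, and Nhlrc3 and Hist1h2al differed in the same direction in microglia. H2-D1, a member of the list that follows, was also higher in microglia and endothelial cells. Whether a genetic difference between the mice or the NPs gave the Colec12 ratio was not tested. Of 11 reactive astrocyte genes 4 were higher and none lower (median 0.53, percentile 99.99, 0.19 to 0.56 over the alternatives), with Cxcl10 9.30-fold, Lcn2 7.52-fold (2.25 to 39.4) and H2-D1 2.39-fold higher, while Gfap was 1.37-fold lower. In the NPs library Cxcl10 and Lcn2 were at 13.5 and 1.13 CPM in astrocytes and at 70.6 and 90.02 CPM in all other cells. Of 10 complement genes 7 were higher (median 0.84, percentile 100), with C1qc at 77.9 and 153 CPM in astrocytes and at 2132 and 2999 in all other cells, and the median was 0.31 with doublets kept. The 16 immediate early and heat shock genes all lay within 1.5-fold (median 0.24, percentile 99.7, -0.01 to 0.24 over the alternatives), Btg2 being 1.498-fold higher.

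In brain endothelial cells 8 of 3319 genes were at least 2-fold higher and 11 lower. Ceacam1 was 2.99-fold, Phactr4 2.46-fold and the cell death gene Pmaip1 2.31-fold higher, and Akr1c14 5.69-fold lower (3.26 to 10.7). Tagln and Acta2, contractile genes of smooth muscle, were 16.9-fold and 8.67-fold lower, with 87.2% and 85.7% of their UMIs in the top 1% of cells. Of 14 blood-brain barrier genes 1 was lower and 13 lay between (median -0.01, percentile 49.8), with the amino acid transporter gene Slc7a5 at 392.2 and 226 CPM and Ocln 1.14-fold lower. Of 8 activation genes 3 were higher and 1 lower (median 0.03, percentile 63.8, 0.02 to 0.51 over the alternatives), with Lrg1 3.91-fold (2.16 to 7.44), Vwf 1.58-fold and Vcam1 1.52-fold higher, the last 2 within 1.5-fold when thinned. Of 18 interferon response genes 3 were lower (median -0.19, percentile 1.65, -0.22 to -0.06 over the alternatives), with Ifi27l2a 1.76-fold lower (-2.87 to -0.0837 on the log2 scale over the alternatives), and of 16 immediate early and heat shock genes 1 was higher and 1 lower (median 0.16, percentile 99.3, -0.10 to 0.37 over the alternatives), Btg2 at 1.67-fold higher, a call lost with doublets kept, and Egr1 at 1.91-fold lower, which turned with the mean over cells. Smooth muscle cells or pericytes carried more Ptgds, a prostaglandin synthase gene (7.73-fold, with 46.0% of its UMIs in the top 1% of cells), and Colec12 (3.10-fold), and less Rasd1 (8.02-fold), Map3k7cl (5.31-fold) and the muscle filament gene Des (4.37-fold lower). Rasd1 was at -0.45 on the log2 scale when thinned, and Trf was 3.03-fold higher but turned under 6 alternatives. Of 1186 genes in smooth muscle cells or pericytes 18 were at least 2-fold higher and 50 lower, and 28 and 26 with the median of all genes (-0.16) set to 0. In neuroblasts, a cluster led by Sox11, Top2a and Mki67, Hist1h2al was 3.21-fold, Fam210b 2.87-fold and Mid1 2.20-fold lower (Hist1h2al -0.31 on the log2 scale when thinned, Mid1 -0.86 with the mean over cells), and Igkc, Ighg2b and Jchain, all far higher, rested on 2 cells. Of 3326 genes there 9 were at least 2-fold higher and 4 lower, and 8 and 9 with the median of all genes set to 0. Xist and Tsix were measured in both brain libraries, Xist at 2768 and 3236 CPM, and Y-linked genes were not.

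T cells of the NPs brain library carried the transcripts of interleukin-17 at a higher level, together with other genes of Th17 cells. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) was at 83.0 and 1164 CPM, 14.0-fold higher (10.96 to 18.2), and Il17f had 0 UMIs in the untreated and 173 in the NPs library, at least 22.2-fold higher. Of 9 Th17 genes 6 were higher and none lower (median 1.84, percentile 100), among them Ahr, 3.76-fold (2.505 to 5.86). Il17a UMIs were found in 2 of 182 T cells of the untreated library (1.10%, 0.133 to 3.91%) and in 94 of 419 of the NPs library (22.4%, 18.5 to 26.7%), at median depths of 3887.5 and 4005 UMIs. In microglia, which lack the gene, 0.0376% and 0.537% of cells had an Il17a UMI at median depths of 4932 and 4707. Of 6 regulatory T cell genes 4 were higher and none lower (median 1.26, percentile 100, and -0.14 when each cell was thinned to 1000 UMIs), with the IL-2 receptor gene Il2ra 6.98-fold (3.29 to 17.7), Ctla4 2.77-fold and Il10 at least 3.59-fold higher (0.53 on the log2 scale when thinned). Of 7 activation genes 5 were higher (median 0.72, percentile 99.97), with Icos 2.51-fold, Tnf 2.23-fold and Pdcd1 2.19-fold higher. Of 11 Th1 and cytotoxic genes 2 were lower and none higher (median -0.36, percentile 0.01), with the perforin gene Prf1 2.37-fold, Klrg1 1.78-fold and Gzma 1.46-fold lower. Ms4a6c was 5.68-fold and Dapl1 3.04-fold lower, as was Ccl3, 4.08-fold, with 53.5% of its UMIs in the top 1% of cells. Of 2117 genes of sufficient level 65 were at least 2-fold higher and 12 lower, the median of all lying 0.15 higher. With that median set to 0 the counts were 51 and 15. The class held 782781 untreated and 2035638 NPs UMIs, so the rule of 100 UMIs favoured higher genes. Jchain, Igkc and Igha were 295-fold (52.8 to 11665), 237-fold and 222-fold higher, but 98.0% of the Igkc UMIs lay in 1 cell.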

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

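The tests of a genetic difference, of handling stress and of a few immunoglobulin-producing cells were chosen only after the result they bear on was seen, and the Hox test was written when Hoxb13 had already been noticed in the epithelium.

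The epithelium of the intestinal libraries differed in many genes, among them Reg3b, Osr2, Atp12a and the interferon response genes. Of the 2-fold genes of the absorptive class 85.3% stayed so at a limit of 10% mitochondrial UMIs. Most of them therefore did not rest on the cells above that limit. The test cannot decide on damage as a whole, because both settings shared cells and damage was read from the mitochondrial share alone. In this class 15 of 16 immediate early and heat shock genes were higher, with a median of 1.03 to 1.60 over the alternatives. Damaged or stressed cells therefore stay open as a cause. The posterior share of Hox UMIs in fibroblasts was 2.857-fold higher in the untreated library, which libraries from different stretches of the intestine could give. The same direction was found in all 6 classes, though part of the Hox RNA in immune cells and in fibroblasts may be free RNA. In the untreated library Hoxb13 was at 122 CPM in fibroblasts and at 326 CPM in absorptive cells. A different stretch could also change the shares of goblet cells, lymphocytes and mast cells and the Reg3 and interferon response genes, so none of the intestinal differences can be assigned to NPs. An effect of the NPs on the epithelium was not tested against this and stays open.

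Microglia differed in few genes, with Cd300lf, Ldhb, Nhlrc3 and H2-D1 higher and Syt6, Hist1h2al and Actn1 lower. Of the 25 genes 2 were immediate early or heat shock genes, Hspa1a and Hspa1b, but that count was chosen with the genes known and the list is short, so it decides nothing about handling stress, which stays open. Of the microglia genes carried by astrocytes or endothelial cells 50.0% (6 of 12, 21.1 to 78.9%) differed alike there, among them Nhlrc3, Trim12c, Hist1h2al, Tpm3-rs7, H2-K1 and H2-D1, which only just met the bound set for a genetic difference between the mice. A treatment effect shared by the classes might give the same value of 50.0%, and genotypes were not read from the transcripts. Whether the interferon response genes of microglia differed because of the NPs was not tested.

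Immunoglobulin transcripts were higher in several classes of the NPs brain library. In microglia 95.42% of the Igkc UMIs lay in 1 cell, which is consistent with an immunoglobulin-producing cell or a doublet inside the class. Carry-over from the NPs intestinal library is unlikely for the bulk of the Igha UMIs, since the brain library held 0.2662% of the epithelial UMIs per Igha UMI of the intestinal library. Most of the 7163 Igha UMIs of the brain library lay in few cells, with 97.2% of the 5208 UMIs of microglia in the top 1% of cells. The ratio therefore cannot decide on carry-over as a source of the low level in all classes. Free RNA might explain the remaining low level in all classes, but the shares of cells with an Igkc UMI differed 1.743-fold between microglia, astrocytes and endothelial cells, a value at which the test could not tell. The origin of these cells stays open.

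The median log2 ratio, NPs over untreated, of 2 lists had opposite signs in intestinal macrophages or monocytes and in microglia. It was 0.38 and -0.07 for the MHC class II list, 0.45 apart (0.4452), and 0.51 and -0.22 for the immediate early and heat shock list, 0.73 apart (0.7261). These are differences between ratios, and levels were not compared between the tissues. The MHC class II difference rests on a median of 0.38 in the intestine that went to 0.0202 with doublets kept. These differences between tissues were not tested, and the length of treatment and possibly the strain of the mice differed with the tissue.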

How the results depend on the processing

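Of the alternatives, those that left out dendritic-like, C1qa-low, interferon-led or Igkc-rich cells or counted unnamed clusters as immune were chosen only after the results were seen. No paired analysis was possible because the groups share replicate number 1 only. A gene or list value counts as turned only where the first choice was past 1.5-fold, a share only where its intervals were apart, so smaller values that changed sign stand among the moved, such as the macrophage cell cycle list (0.66) and interferon list (-0.43) without dendritic-like sub-clusters. Of 320 share values 232 stayed, 81 moved and 7 turned direction, of 612 list values 457, 154 and 1, of 3801 gene values 3107, 660 and 34, and of 28 gene counts 27, 1 and 0. Thinning to 1000 UMIs moved most (169 moved, 7 turned), then the mean over cells (117 and 3), doublets kept (76 and 5), separate clustering (74 and 8) and the limit of 10% mitochondrial UMIs (72 and 6), and of those chosen beforehand the lower UMI minimum least (3 and 0). The macrophage or monocyte share of immune-like cells, 42.92 points higher, went to 48.85 at resolution 0.5 and 38.71 with separate clustering. The IL-1 list of that class went from -0.05 to -0.31 with the median of gene ratios as scaling and to -0.25 with separate clustering, its 336 of 1329 genes to 86 of 211 when thinned, and the disease-associated list of microglia from 0.0303 to 0.0565 with the mean over cells. Turned in the intestine were these values. With a 10% limit: plasma cell share 0.415, Clu in fibroblasts 1.76, Ifit1 in macrophages 0.0134, Il22 in T cells 2.29, Ikzf2 -0.30. With no limit: T cell share of immune cells 1.77, Ifit1 0.0269, Il17a 1.63, Il22 3.26. With doublets kept: absorptive share -10.2, plasma cell share 0.0734, Il17a 2.10, Il22 2.09. With separate clustering: NK cell or ILC share of immune cells -2.46, T cell share 10.7, Cox6a2 0.73, Siglech 0.67, Il17a 0.69, Il22 4.51, Ube2c -0.96. Thinned: Ifit2 -0.31, Gclm -0.0468, Il22 1.57. At resolution 0.5 Ifit1 was 0.0335, at resolution 2 Ikzf2 -0.25, and with the mean over cells Gclm -0.31. With unnamed immune clusters counted Ikzf2 was -0.33 and the T cell share 0.0121, and without dendritic-like sub-clusters Siglech was 0.24. Turned in the brain were Trf in smooth muscle cells at -0.20 (10% limit), -0.43 (no limit), -0.81 (doublets kept) and -0.23 (resolutions 0.5 and 2 and separate clustering), the regulatory T cell list at -0.14, Ifi47 in endothelial cells at 1.63 and Cp in astrocytes at -0.0438 when thinned, Cd74 in endothelial cells at 0.40 (mean over cells) and 0.46 (thinned), Egr1 there at 0.0516 (mean over cells), and Ifit1 in microglia at -0.27 without the interferon-led cluster. Why they turned was not examined, so the cause was not tested. Without C1qa-low sub-clusters 21 untreated macrophages were left, under the minimum of 50, so lists and genes gave no value there, and the gene count, 275 higher and 7 lower of 876, was taken below that minimum. No value could be given for the NK cell or ILC share with no mitochondrial limit or at resolution 0.5, neuroblasts in several settings, smooth muscle genes at 1000 UMIs, fibroblast genes with doublets kept, Ly6d in 5 settings, and, when thinned, the macrophage cell cycle list, the endothelial activation list and Lrg1, nor for Ighg2b in neuroblasts without Igkc-rich cells.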

Other observations

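The shares of T cell genes by Il17a and the gene table of the Il17a-bearing cells were chosen only after Il17a was seen, while the test of gamma-delta T cells was written before.

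In the NPs brain library the T cells with an Il17a UMI differed from the other T cells in lineage genes. Cd4 was found in 46.8% of the 94 cells with Il17a and 24.0% of the 325 without, and Cd8a in 3.19% and 36.9%. Il2ra was found in 42.6% and 11.7%, the tissue homing receptor gene Cxcr6 in 95.7% and 50.8% and Ccr6 in 21.3% and 6.15%. Trac, the constant gene of the alpha chain of the T cell receptor, was found in 87.2% and 78.2%.

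More gamma-delta T cells are unlikely to account for Il17a by Trdc, since the share of cells with a Trdc UMI in T cells with Il17a was 0.7858 of that in T cells without it (5.32% and 6.77%). Tcrg-C2 (1.91-fold), Tcrg-C4 (2.01-fold), Trgv2 (4.42-fold), Blk (5.19-fold) and Cd163l1 (3.85-fold), however, were higher in the T cells of the NPs library and are known from such cells, so a part may still belong to them. An effect of the NPs on T cells of the brain, and blood or meninges left in the tissue, were not tested.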
